A study of Mus musculus with 8 samples.

How the data were processed

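RNA was measured in 8 libraries of cultured mouse tail tendon fibroblasts, 4 Scx-positive and 4 Scx-deleted, grouped by the genotype in the labels. Per the labels' protocols, total RNA came from a miRNeasy Micro kit with DNase I, and libraries followed Illumina protocols. Per the submitters' processing notes, STAR, DESeq2 and FastQC were used with the mouse build mm10. Their roles and versions, the read counter, the annotation and the use of strand are not given in the sources used here. Genes that share sequence or overlap on opposite strands can therefore carry uncertain counts.

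The authors deposited a table of whole-number counts per gene symbol, not normalized, which fed every test. It held 24982 genes and a row each for reads in no feature and ambiguous reads. Those rows took 8.30% ± 0.542 and 0.496% ± 0.00696 of the counts in Scx-positive and 7.73% ± 0.375 and 0.549% ± 0.0126 in Scx-deleted libraries (SD, n = 4 each) and were left out. Depth ranged from 17343228 to 25180790 gene counts per library. The authors' deposited comparison table holds normalized mean counts, a coverage-type signal, with a log2 fold change, a standard error and a test statistic, which are scores, and a p-value with its adjusted value, per the file headers. The direction of its log2 fold changes was read from their sign against the fit of the counts. Its mean signal was 1.26 times the mean count at the median gene, and some genes high there had 0 counts here, so it was made from other counts. It was used only for comparison, and 2 of its columns, whose names do not show a group, were not used.

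Symbols were matched to GENCODE mouse release 21 on GRCm38, which placed 24490 of 24982 (98.0%). Counts were tested in R 4.3.3 with edgeR 4.0.16. Genes passed filterByExpr with its minimum count of 10 and total of 15, which left 13125, and TMM factors scaled the libraries. A quasi-likelihood fit with group as the only term gave log2 changes of Scx-deleted over Scx-positive cells, with Benjamini-Hochberg adjustment at 0.05. Standard errors are the log2 change divided by the square root of F. The common biological coefficient of variation was 5.50%. Levels are CPM with TMM factors. The interval of the Scx ratio is exact (Clopper-Pearson) at 95% and covers counting error only, since reads without molecular identifiers are not independent molecules.

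The main tests, alternatives, gene lists and naming rule were fixed before the data were examined. Of 38 gene lists, 34 with at least 5 tested members were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01. Camera with an estimated correlation and fry were alternatives. Genes were named as follows: Scx and Bop1, and the 12 largest rises and 12 largest falls among called genes with a mean of at least 2 CPM and groups that did not overlap. Predicted genes, pseudogenes and sex-linked markers were left out of those. Up to 4 members with the smallest p came from each list called or holding a called gene. Tnmd, Mkx, Col1a1, Col1a2, Col3a1, Mcam, Tcf15 and Thbs4 were always included, and so were up to 3 genes per direction called only in the authors' deposited table. A few genes that the rule names are not reported here, but they stay in every count.

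Alternatives were RLE and upper-quartile scaling, no filter and a filter of 5 CPM in 4 libraries, DESeq2 1.42.0, limma-voom with and without sample weights, the replicate number as a block, numbers 2, 3 and 5 alone, 1 surrogate variable from sva 3.50.0, adjusted p of 0.01 and 0.1, a 1.5-fold threshold, and each library left out. A correction for GC content and transcript length, thinning to equal depth, and leaving out Scx-positive 5 with Scx-deleted 4 were added after the data were seen. The fit with sex as a covariate was not run, because neither group held both sexes by Xist and Y-linked counts.

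The fit was tested on simulated counts of 13057 genes drawn from these libraries' means and depths. Known changes were planted in 67 genes at 1.25-fold, 66 at 1.5-fold and 64 at 2-fold, and in 1 list. That is a far smaller share than was called in the real data, where recovery and false calls could differ. The fit recovered 74.6% of genes changed 1.25-fold, 87.9% at 1.5-fold and 96.9% at 2-fold, and 5.47% of its calls were false. Within groups no pair of libraries was closer than sampling noise, so each counted as a replicate. Nothing in the labels says that the libraries came from separate animals or cultures, so p-values measure the spread between these libraries, which may be technical.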

Results

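Gene expression was measured by RNA sequencing in cultured mouse tail tendon fibroblasts of the C57Bl/6 strain that kept the gene Scx or had lost it. Scx encodes scleraxis, a basic helix-loop-helix transcription factor of tendon cells. All 8 samples had received 4-hydroxytamoxifen (4HT) according to the labels, so the treatment was shared by both groups. There were 4 Scx-positive libraries, numbered 2, 3, 5 and 6, and 4 Scx-deleted libraries, numbered 2, 3, 4 and 5. Gene counts per library ranged from 17343228 to 25180790, with 22344700 ± 2838330 (SD, n = 4) in Scx-positive and 20209644 ± 2130422 (SD, n = 4) in Scx-deleted libraries. The series asks which mRNAs differ between tendon cells with and without Scx.

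Scx itself separated the groups. The Scx-positive libraries 2, 3, 5 and 6 held 177, 132, 252 and 156 Scx counts, and the Scx-deleted libraries 2, 3, 4 and 5 held 3, 1, 2 and 3. The Scx level was 7.92 ± 1.52 CPM (SD, n = 4) with the gene and 0.112 ± 0.0461 CPM (SD, n = 4) without it. Summed over libraries and scaled for depth, the Scx-deleted cells had 1.39% of the Scx-positive level, with an exact 95% interval of 0.635% to 2.66% that covers counting error only. The log2 change was -6.08 ± 0.27 (SE), with an adjusted p of 1.75e-09 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Scx (ENSMUSG00000034161.8) has 2 exons on the plus strand of chromosome 15, between 76457452 and 76459458 of GRCm38. It lies inside an intron of Bop1 (ENSMUSG00000022557.11), a ribosome biogenesis gene on the minus strand from 76452989 to 76477277. Exon 4 of Bop1 ends at 76456026 and its exon 3 starts at 76466772, so no Bop1 exon of that transcript overlaps Scx. Bop1 stood at 81.4 ± 5.87 CPM in Scx-positive and 83.0 ± 3.23 CPM in Scx-deleted cells (SD, n = 4 each), a log2 difference of 0.03 ± 0.05 (SE) that did not pass the test. The deleted part of Scx is not given in the labels, so reads from a remaining part could be counted.

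Across the transcriptome, 1842 genes were higher and 1902 lower in Scx-deleted cells, out of 13125 tested by edgeR at an adjusted p under 0.05. Most of these changes were small, with a median absolute log2 change of 0.31, and 80 genes rose and 111 fell by at least 2-fold. The groups did not overlap in 3823 of the 13125 tested genes, where chance gives 2.86% of genes. The first principal component of log2 CPM held 53.3% of the variance and separated the groups. Scx-positive replicate 5 stood apart from the other Scx-positive libraries on the second component, which held 12.9%. Without that library 2409 genes were higher and 2310 lower, and after a correction for GC content and transcript length 3109 were higher and 1985 lower. With upper-quartile scaling 1539 were higher and 2288 lower, or 40.2% higher against 49.2% with TMM.

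**Figure D1:**
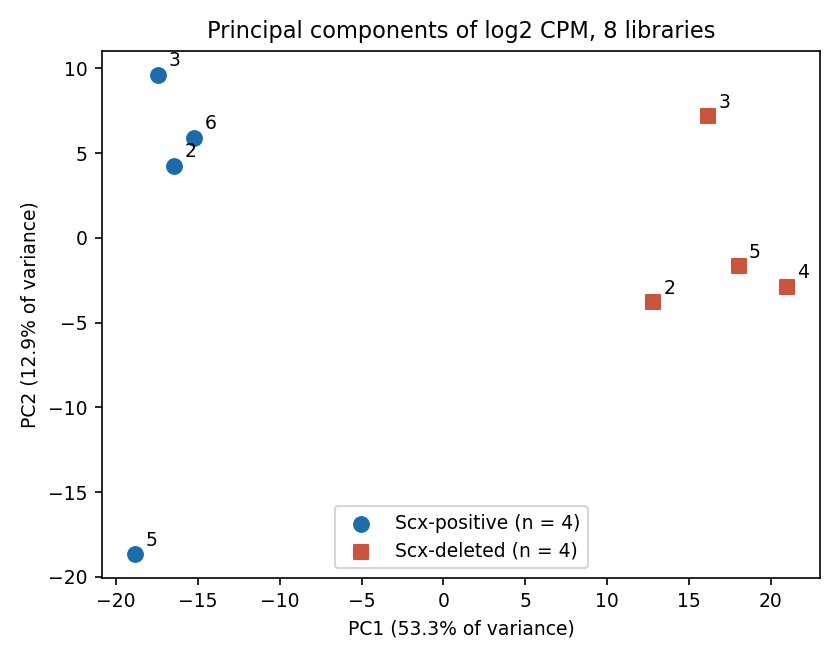
Principal components 1 and 2 of log2 CPM for the 4 Scx-positive (circles) and 4 Scx-deleted (squares) libraries, labelled by replicate number, with the percent of variance on each axis. The groups separate on component 1 (53.3%), and Scx-positive replicate 5 lies at -18.6 on component 2.

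Among genes with a mean of at least 2 CPM, the largest falls after Scx included genes of matrix proteins and of receptors. Clec3b, which encodes tetranectin, went from 8.33 ± 2.83 to 0.948 ± 0.415 CPM, and the ferritin receptor gene Scara5 from 39.1 ± 7.49 to 4.98 ± 0.568 CPM (SD, n = 4 each). Eln, the gene of elastin, had a log2 change of -2.84 ± 0.21 (SE), from 84.9 ± 29.1 to 11.7 ± 2.93 CPM. Pi16 had a log2 change of -2.35, the collagen gene Col8a2 -2.16, and Aspn, a small leucine-rich proteoglycan, -2.10. Dner (-1.96), St8sia2 (-1.75), Susd2 (-1.73) and Arsi (-1.65) were also among the 12 largest falls, which include Scx. Every one of the 4 Scx-deleted libraries lay below every Scx-positive library for each of these genes, which the naming rule required.

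Among genes with a mean of at least 2 CPM, the 12 largest rises included a hydroxysteroid dehydrogenase gene and matrix metalloproteinase genes. Akr1c18 rose from 0.701 ± 0.183 to 3.57 ± 1.06 CPM, a log2 change of 2.31 ± 0.26 (SE). Mmp10 rose by 2.23 ± 0.11 on the log2 scale, from 2.87 ± 0.513 to 13.6 ± 0.997 CPM, and the collagenase gene Mmp13 by 2.05 ± 0.19, from 2.95 ± 0.992 to 12.2 ± 2.62 CPM (SD, n = 4 each). The secreted glycoprotein gene Stc2 rose by 1.75 ± 0.08, from 18.03 ± 1.56 to 60.3 ± 6.74 CPM. The other rises were Crct1 at 1.81, the deiodinase gene Dio2 at 1.70, the prolactin receptor gene Prlr at 1.69, and Mylk2 at 1.64. Rragd, Syngr1 and Clec2h each had a log2 change of 1.53 and Ifi207 of 1.51.

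**Figure D2:**
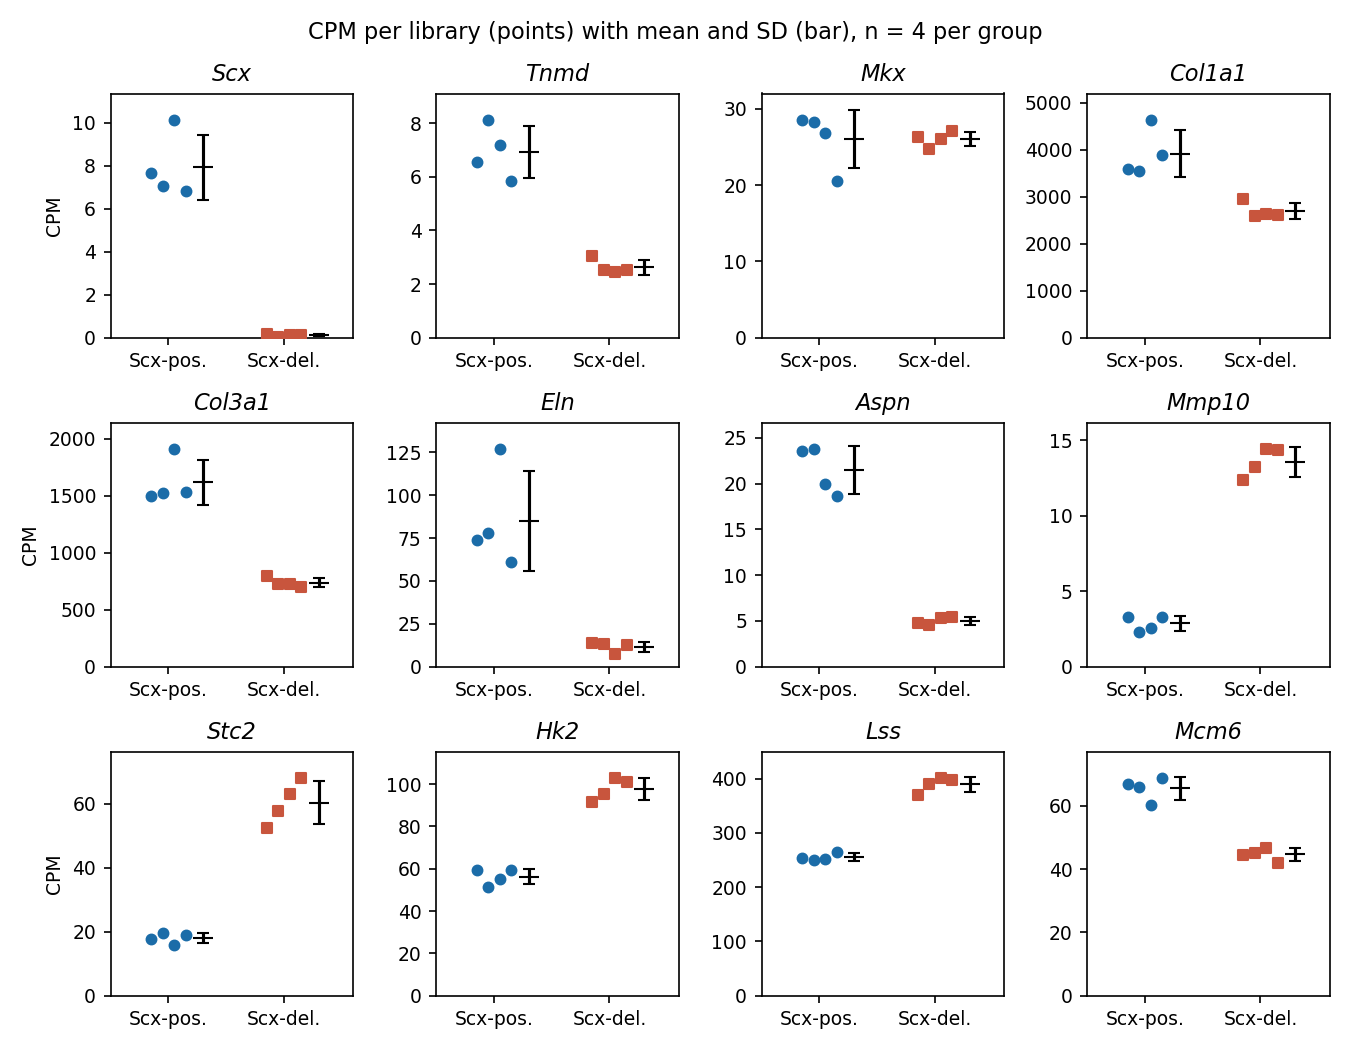
CPM of 12 genes in each library (points) with the mean and SD of each group (bars), 4 libraries per group, on linear axes that start at 0. Scx, Tnmd, Col1a1, Col3a1, Eln, Aspn and Mcm6 are lower in all Scx-deleted libraries, Mmp10, Stc2, Hk2 and Lss are higher, and Mkx (26.0 and 26.1 CPM) overlaps.

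Tendon genes fell in part. Tnmd, which encodes tenomodulin, went from 6.93 ± 0.972 to 2.63 ± 0.274 CPM, a log2 change of -1.39 ± 0.13 (SE), and Comp, a cartilage and tendon matrix protein, changed by -1.57 ± 0.14. Col14a1 (-1.25), Tgfb2 (-0.89) and Thbs4 (-0.58) fell as well. Mkx, a homeobox transcription factor of tendon, stood at 26.0 ± 3.75 and 26.1 ± 0.951 CPM (SD, n = 4 each) and did not pass the test, and Tnc, the gene of tenascin C, rose by 0.63 ± 0.05. Of 22 tested members of the tendon lineage list 12 fell and 2 rose, and 13 fell and 2 rose adjusted over the list alone. The count that rose was 1 without Scx-positive replicate 2 or 6 and without Scx-deleted replicate 2, 3 or 4. The list was lower by limma's camera with a preset correlation of 0.01 (Benjamini-Hochberg adjusted p = 1.62e-05), with an adjusted p = 0.327 with an estimated correlation. Comp was highest in Scx-positive replicate 5 at 56.3 CPM against 33.6 to 37.2 CPM in the other Scx-positive libraries.

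Most genes of fibrillar collagens, the main load-bearing proteins of tendon, fell. Col3a1 went from 1617 ± 199 to 736 ± 40.6 CPM, a log2 change of -1.14 ± 0.07 (SE), and Col11a1 changed by -0.85 ± 0.05. Both chains of type I collagen fell, Col1a1 by 0.54 ± 0.07 and Col1a2 by 0.40 ± 0.06 on the log2 scale, and Col5a1 changed by -0.47. Of 11 tested members 8 fell and 0 rose, and 9 fell adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 2.19e-05, and adjusted p = 0.215 with an estimated correlation). In the small leucine-rich proteoglycan list, proteins that bind collagen fibrils, 7 of 11 members fell and 0 rose, and 7 fell adjusted over the list alone. Ogn changed by -1.20, Fmod by -1.08 and Dcn, the gene of decorin, by -1.01. The camera adjusted p was 1.33e-05, with an adjusted p = 0.215 with an estimated correlation. Col3a1 was also highest in Scx-positive replicate 5, at 1914 CPM against 1495 to 1534 CPM in the other Scx-positive libraries.

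Some genes for collagen processing and elastic fibres fell. Of 28 collagen maturation genes 13 fell and 0 rose, and 14 fell adjusted over the list alone, among them Loxl2 (-0.45), P3h4 (-0.32), Adamts3 (-1.31) and P4ha3 (-0.87). Of 16 elastic fibre genes 8 fell and 0 rose, and 8 fell adjusted over the list alone, among them Eln, Fbn1 (-0.32), Ltbp2 (-0.47) and Emilin1 (-0.37). The camera adjusted p was 2.34e-05 and 0.00113 for these lists, with adjusted p = 0.440 with an estimated correlation for each. The non-fibrillar collagens were not called as a list, although Col12a1 (-0.45) and Col6a1 (-0.58) fell, and 8 of 21 members fell and 3 rose, with 9 lower and 3 higher adjusted over the list alone. Their camera adjusted p was 0.0768, and it became 0.0416 without Scx-positive replicate 2, 0.0327 without Scx-positive replicate 3 and 0.0181 without Scx-deleted replicate 4. It was 0.0115 with the stricter filter on low counts and all 8 libraries, and 0.0324 with numbers 2, 3 and 5 only, with the list lower each time.

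Matrix proteases and their inhibitors went both ways. Mmp10, Mmp13, Mmp3 (1.28) and the cathepsin gene Ctsk (0.80) rose, and the aggrecanase gene Adamts5 changed by -0.63. Of 34 members 10 rose and 14 fell, with the same counts adjusted over the list alone, and the list was not called. Its median log2 change was -0.04 and its mean 0.11, which differ in sign. The median was 0.02 without Scx-positive replicate 5 and 0.03 after correction for GC content and transcript length. Among hyaluronan and large proteoglycan genes 5 of 12 fell and 1 rose, including the hyaluronan synthase Has2 (-0.74), Itih5 (-0.85) and Prg4 (-0.45), while the hyaluronan receptor gene Cd44 rose by 0.36. Adjusted over the list alone 5 fell and 2 rose. Adjusted over all genes, 3 rose without Scx-positive replicate 5, and 3 fell without Scx-positive replicate 6 or Scx-deleted replicate 5. Of 33 basement membrane and integrin genes 10 fell and 4 rose, with equal counts adjusted over the list alone, led by Lama4 (-0.86), Itgb7 (0.70), Nid2 (-0.67) and Itga7 (0.53). Leaving out Scx-positive replicate 5 gave 12 lower and 7 higher.

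Most members of the sterol and sugar metabolism lists rose. In the cholesterol synthesis list 22 of 24 members rose and 0 fell, and 22 rose adjusted over the list alone. Lss, the lanosterol synthase gene, rose from 256 ± 6.88 to 390 ± 14.2 CPM (SD, n = 4 each), a log2 change of 0.61 ± 0.04 (SE), with Fdft1 at 0.57, Insig1 at 0.48 and Nsdhl at 0.42. The camera adjusted p was 1.74e-14, with an adjusted p = 0.215 with an estimated correlation. In the glycolysis and hypoxia list 19 of 30 members rose and 0 fell, and 22 rose adjusted over the list alone. Hk2, the gene of hexokinase 2, rose by 0.79 ± 0.05, from 56.3 ± 3.70 to 97.7 ± 5.23 CPM, with Ankrd37 at 1.29, Aldoc at 0.72 and Ero1l at 0.46. The camera adjusted p was 1.54e-09, with an adjusted p = 0.215 with an estimated correlation. Of 25 fatty acid synthesis and oxidation genes 6 rose and 2 fell, among them Acly (0.28), Elovl6 (0.26) and Acadvl (-0.19). Adjusted over the list alone 8 rose and 2 fell, and the list was not called. Without Scx-deleted replicate 3, 4 or 5 the count that fell was 1.

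Cell cycle genes were lower by small amounts in nearly the whole list. Of 42 members 39 fell and 0 rose, and 39 fell adjusted over the list alone, with a median log2 change of -0.38. When Scx-positive replicate 5 was left out 40 fell and 1 rose. The replicative helicase genes Mcm6 and Mcm5 changed by -0.55 ± 0.05 and -0.64 ± 0.07 (SE), the ribonucleotide reductase gene Rrm1 by -0.46, and the cyclin gene Ccne2 by -0.96. The camera adjusted p was 8.33e-14, with an adjusted p = 0.432 with an estimated correlation. Growth factor genes fell more often than they rose, with 14 lower and 5 higher of 34, and 15 lower and 7 higher adjusted over the list alone. Igf1 changed by -1.06 ± 0.10, Fgf18 by -1.20, Kitl by -0.54 and Wnt5a by -0.51. Their camera adjusted p of 0.0282 (adjusted p = 0.215 with an estimated correlation) became 0.0554 without Scx-positive replicate 5 and 0.0513 with upper-quartile normalization, and other settings ended the call too.

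**Figure D3:**
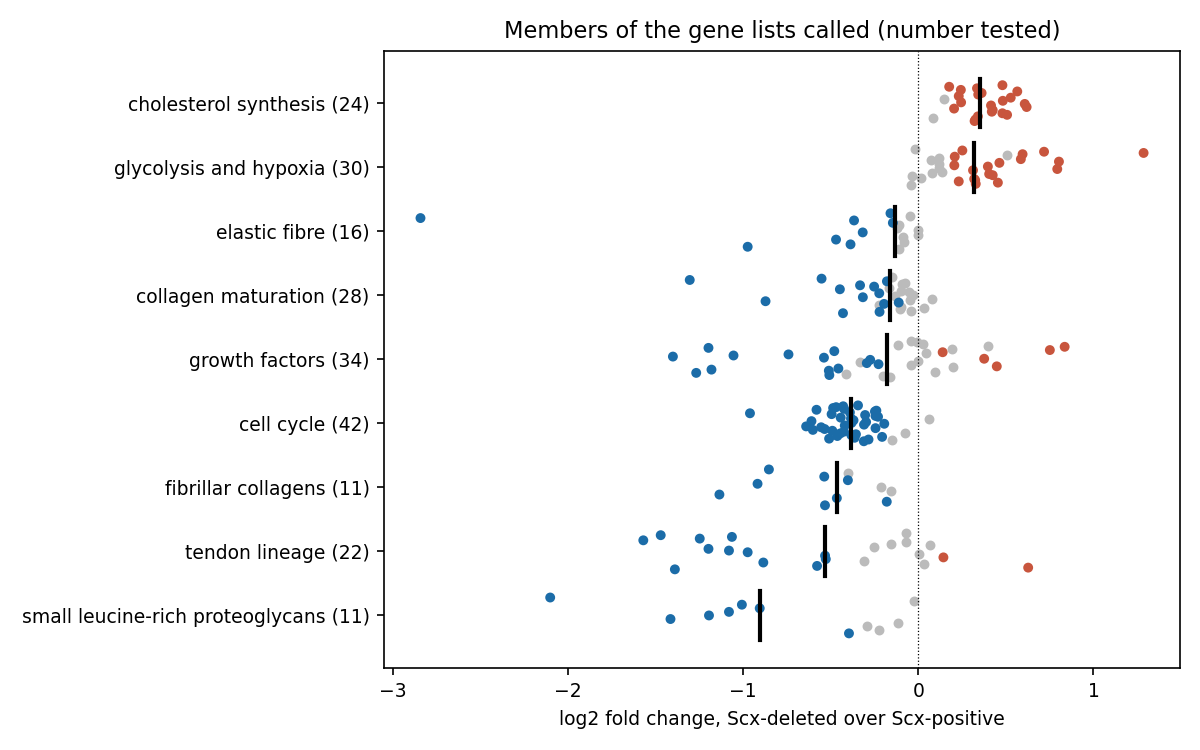
Log2 fold changes of Scx-deleted over Scx-positive cells for the tested members of the 9 gene lists called by camera with a preset correlation, with the list's median as a black bar and its number tested in brackets. Red points rose and blue points fell at an adjusted p under 0.05 in edgeR, and grey points did not pass. Medians run from -0.91 for small leucine-rich proteoglycans to 0.35 for cholesterol synthesis.

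With an estimated correlation camera called 0 of the 34 tested lists at an adjusted p under 0.05, with 5 lists at an unadjusted p under 0.05. The smallest adjusted p was 0.215, while limma's fry, which compares no list with the other genes, called 20. Of the 35 ways to split the 8 libraries into 4 and 4, 11 called at least 9 lists by camera with the preset correlation, the real one included. The others among these 11 held unequal numbers of Scx-positive and Scx-deleted libraries on each side, so part of the group difference remained in them. Splits with equal numbers called 5 or fewer lists. Since the list calls depend on the assumed correlation, the counts of called members are given with each list.

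Signalling lists were mixed. In the TGF-beta and BMP list 14 of 45 members fell and 7 rose, and 19 fell and 8 rose adjusted over the list alone. The BMP antagonist Grem1 rose by 0.92, while Id4 changed by -0.59. Among p53 and DNA damage genes 10 of 26 rose and 2 fell, led by Gadd45a (0.53), Mdm2 (0.31), Plk3 (0.31) and Plk2 (0.23). Of 26 interferon response genes 8 rose and 1 fell, led by Ifit3, which rose by 1.28 ± 0.08 (SE) from 50.5 ± 5.59 to 123 ± 11.8 CPM, and Ifit2 (0.66). Adjusted over the list alone, the p53 and interferon counts were the same. Of 24 inflammatory cytokine genes 9 rose and 4 fell, with 9 and 5 adjusted over the list alone, led by Cxcl12 (0.67), Ccl2 (0.39), Vcam1 (-0.46) and Cxcl1 (-0.86). None of these lists was called by camera in the main fit, although other camera settings called the p53 and interferon lists. The fry test called the TGF-beta and BMP (adjusted p = 0.00734), p53 (0.00833) and cytokine (0.0404) lists and not the interferon list (0.187). The interferon count that rose was 5 without Scx-positive replicate 2 or 6, and 4 with numbers 2, 3 and 5 only. The interferon list had an adjusted p of 0.147, which became 0.0353 without Scx-deleted replicate 4. The p53 list had 0.0623, which became 0.0470 without Scx-positive replicate 2, 0.0327 without Scx-deleted replicate 3 and 0.0334 without Scx-deleted replicate 4. It was 0.0261 with no filter on low counts and 0.0371 with a surrogate variable, both with all 8 libraries, and 0.0276 without Scx-positive 5 and Scx-deleted 4. Both lists were higher in these fits.

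The unfolded protein and amino acid list had 7 of 30 members higher and 3 lower, with 7 and 4 adjusted over the list alone, led by Ddit3 (0.71), Phgdh (0.41) and Chac1 (0.55). Among immediate early genes 4 of 25 rose and 5 fell, with 5 and 5 adjusted over the list alone, including Fosl1 (0.50) and Klf2 (-0.81). Of 32 axon guidance and nerve growth genes 5 rose and 10 fell, with equal counts adjusted over the list alone, including the neuropilin genes Nrp2 (0.52) and Nrp1 (-0.52). The contractile list had 3 of 18 lower, the YAP and mechanical response list 3 of 19 higher and 3 lower, and the bHLH relatives of Scx 1 of 14 higher and 2 lower, with equal counts adjusted over each list alone. Bhlhe40 rose by 0.51, Atoh8 changed by -0.40, and Synpo2 by -0.71. None of these lists was called by camera with all libraries. The contractile count was 7 without Scx-positive replicate 2, 5 without Scx-deleted replicate 2 and 1 without Scx-deleted replicate 5. The contractile adjusted p of 0.116 became 0.0153 without Scx-positive replicate 2, with the list lower. In the unfolded protein list 1 fell without Scx-positive replicate 2 or without Scx-deleted replicate 3, 4 or 5. Of the immediate early genes 3 fell without Scx-deleted replicate 2 or 5, and 3 of 15 bHLH relatives rose without Scx-positive replicate 5.

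Markers of other lineages did not move in a single direction. Cartilage genes had 3 of 14 higher and 4 lower, bone genes 1 of 8 higher and 3 lower, and fat genes 7 of 17 higher and 2 lower. Sox5 (0.64), Plin4 (0.68) and Pparg (0.53) were among those that rose, and Spp1 (0.63) was the bone gene that rose. Comp (-1.57) and Col11a1 (-0.85) were among the cartilage genes that fell. The fat list's median (-0.05) and mean (-0.06) were below 0 while its direction by camera was up. In the sheath and synovial lining list 7 of 15 fell and 3 rose, with Pi16, Sema3c (-0.75) and Cd55 (-0.46) lower and Clic5 (1.22) higher. Mural cell and pericyte markers had 4 of 14 higher and 5 lower, with 4 and 7 adjusted over the list alone, and Mcam stood at 26.3 ± 3.21 and 27.3 ± 3.60 CPM (SD, n = 4 each) without passing the test. Macrophage and leukocyte markers had 2 of 6 higher and 1 lower, and endothelial markers 3 of 7 higher and 2 lower. Skeletal muscle markers had 1 of 5 lower, Schwann and glial markers 1 of 10 lower, and keratinocyte markers 0 of 4 changed. Tail and limb position genes had 1 of 13 higher and 2 lower. For the lists in this paragraph other than the mural list, the counts were the same adjusted over each list alone. The keratinocyte list had too few tested members for camera, which called none of the other lists of this group in the main fit. The fry test called the cartilage (adjusted p = 0.00101) and sheath (0.00784) lists, and other camera settings called the sheath and synovial lining list. Its camera adjusted p of 0.0892 became 0.0295 after correction for GC content and transcript length with all 8 libraries, 0.0303 without Scx-positive replicate 6 and 0.0234 with numbers 2, 3 and 5 only, with the list lower each time. Cd14, a leukocyte marker, was at 14.3 ± 0.804 and 15.1 ± 0.851 CPM (SD, n = 4 each) and did not pass the test. Xist, the only sex-linked marker tested, changed by -0.26, and all 8 libraries held 2 or fewer Y-linked counts. Tcf15 did not pass the filter on low counts, and 0 red blood cell or mitochondrially encoded genes of the lists were tested.

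Several counts of these markers moved by over 1.5 times when 1 library was left out. Cartilage genes had 2 lower without Scx-positive replicate 2 or without Scx-deleted replicate 3 or 5, and 1 higher without Scx-positive replicate 6. Fat genes had 4 higher without Scx-deleted replicate 4 or 5, and 4 lower without Scx-positive replicate 2. Endothelial markers had 1 of 7 higher without Scx-deleted replicate 4. The count of skeletal muscle markers lower was 0 without Scx-positive replicate 6 or without Scx-deleted replicate 3 or 5. Schwann and glial markers had 2 lower without Scx-positive replicate 2 or 3 or Scx-deleted replicate 3, and 1 higher without Scx-positive replicate 5 or Scx-deleted replicate 3. Keratinocyte markers had 1 higher and 1 lower without Scx-positive replicate 3 and 1 lower without Scx-deleted replicate 5. Tail and limb position genes had 0 higher without Scx-positive replicate 2 or 6 or Scx-deleted replicate 5. They had 1 lower without Scx-positive replicate 2 or 5 and without each of the Scx-deleted replicates.

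The authors' deposited table gave 2198 genes higher and 2041 lower among 14511 genes. Over the 13110 genes tested in both, its log2 changes and those of the edgeR fit had a Pearson r of 0.968 across genes, which are not independent replicates. Both called 3335 genes, all in the same direction, with 408 called by edgeR alone and 833 in the authors' deposited table alone. The shared direction is no independent check, since that table describes the same series and its direction was read from the edgeR fit. The 3 largest rises and 3 largest falls called in the authors' deposited table and not by edgeR were outside these 13110 genes, since low counts left them untested by edgeR. In the authors' deposited table Mlana was at 2.78, Trpc4 at 2.80 and Erv3 at 4.02, and Apol7b at -3.02, Agtr2 at -2.69 and Pipox at -2.38, on 72 or fewer counts over all 8 libraries.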

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

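The test of a common fall of tendon and matrix genes and the test against the authors' deposited table were chosen after the results were seen. The correction for GC content and length, thinning and the removal of a pair of libraries were added then too.

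Among 332 groups of 4 libraries checked, over every named gene and several measures per library, 21 held a library far from the other 3, where chance flags about 1 in 20 groups, or 16.6. Scx-positive replicate 5 accounted for 8 of these. It was highest of its group for Col3a1 (1914 CPM), Susd2 (18.2 CPM), Comp (56.3 CPM), Col6a1 (464 CPM), Plin4 (43.5 CPM) and Klf4 (349 CPM), and lowest for Kitl (147 CPM) and Cxcl1 (4.19 CPM). Scx-deleted replicate 2 was highest for Tnmd (3.04 CPM), Col1a1 (2961 CPM) and Ltbp2 (419 CPM) and lowest for Nrp2 (665 CPM). Scx-deleted replicate 4 was lowest for Eln (7.37 CPM) and highest for Itgb7 (51.7 CPM), Egfl7 (5.11 CPM) and the ribosomal RNA precursor Rn45s (37.1 CPM). Scx-deleted replicate 5 was lowest for Angpt1 (2.25 CPM) and highest for Hoxa11 (14.98 CPM). Scx-positive replicate 3 was lowest for Akr1c18 (0.428 CPM) and Ngfr (28.4 CPM). A further 96 genes had a mean over 50 in the authors' deposited table while their counts summed to under 20 over all 8 libraries, among them Hmga1b and Rps27rt, chosen for their high means there.

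The gene counts stood out from other groupings of the libraries. Of the 35 splits of the 8 libraries into 4 and 4, 1 gave as many genes higher and 1 as many lower, the real split in each case. The real split had 1842 higher and 1902 lower and the highest other split 0 by edgeR. Every other split holds libraries of both groups on each side, which adds the group difference to the spread. Few calls were therefore likely there in advance, and 1 of 35 is the smallest share possible, so the splits cannot exclude chance. The other splits had 60 to 2477 genes at an unadjusted p under 0.05 by edgeR, and limma-voom called 0 in each. The count of gene lists was not the highest. The real split called 9 lists by camera with the preset correlation. As many were called in 11 of the 35 splits, the real one included, and the highest other split called 13. The others among these 11 held unequal numbers of Scx-positive and Scx-deleted libraries on each side, so part of the group difference remained in them. Splits with equal numbers called 5 or fewer lists. Neither kind of split is a clean reference for chance. Chance cannot be excluded for the number of lists. Since edgeR called 0 genes in every other split, the absence of called list members there adds nothing.

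In the tendon lineage, fibrillar collagen and small leucine-rich proteoglycan lists more genes fell than rose. A smaller share of tendon fibroblasts would lower all of them alike only if the other cells expressed none of them. The 95% interval excluded the median change of -0.53 in 25 of the 43 tested members (9 above it and 16 below). Expression in other cells of the cultures is not known here, so the unequal changes do not decide this explanation. With the trend on GC content and length taken out, the medians went from -0.53, -0.47 and -0.91 to -0.51, -0.36 and -0.81 and the largest adjusted p of the 3 lists by camera with the preset correlation was 1.63e-05 (with an estimated correlation and no such correction 0.327, 0.215 and 0.215), which argues against that trend as the whole cause. The explanation by reads shared between near-identical genes stays open: 0 of 28 called members had the opposite sign in the authors' deposited table, but no gene called in both did, and sharing need not turn a sign. The loss of Scx stays open as a biological explanation, as a hypothesis that these data alone cannot separate from any culture difference shared by a whole group.

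Cell cycle genes were lower. With every library thinned to equal depth 38 of the members were still lower, which argues against depth as the cause. Without Scx-positive 5 and Scx-deleted 4 the number was 41. That removal cannot test those libraries as causes, because it widened the gap between the groups. Scx-positive 5 had the lowest mean cell cycle level of its group (5.12 log2 CPM) and Scx-deleted 4 the highest of its group (4.95). With each library left out in turn 33 to 40 members were lower, which argues against any single library as the whole cause. Growth state or density at harvest stays open. Within groups, the libraries' cell cycle and matrix levels had a Pearson r of -0.70 (exact permutation p = 0.0920) and a Spearman rho of -0.74 (exact permutation p = 0.0694) over 8 libraries. The sign is opposite to the difference between groups, where both levels were lower in all Scx-deleted libraries. The relation rests on 2 libraries, since r was -4.65e-05 without the 2 farthest from the median, and a density difference between whole groups was not tested.

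Cholesterol synthesis genes were higher. After the GC content and length trend was taken out the median log2 change was 0.36 against 0.35 before, and the adjusted p by camera with the preset correlation was 1.91e-13 (0.215 with an estimated correlation and no such correction), which argues against that trend as the whole cause. Lower cellular sterol, with lower activity of the liver X receptors, may be a candidate explanation. The receptor target Abca1 was called lower, and it was left out because that was seen before the test. Of 8 other receptor targets tested, 1 was called lower and 0 higher. Chance gives 1.16 called lower, so the written bound was met by a single gene (Smpdl3a, like Abca1 chosen after its values were seen) and the test decided nothing. Medium, serum or density differences between the groups were not tested.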

How the results depend on the processing

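The GC content and length correction, thinning and the removal of Scx-positive 5 with Scx-deleted 4 were chosen after the data were seen. The Scx log2 change stayed between -6.17 and -5.77 over the alternatives other than leave-one-out and between -6.25 and -5.82 with each library left out. Leaving out each library gave 1447 to 2409 genes higher, 1427 to 2310 lower and 8 to 12 lists called, both highest gene counts without Scx-positive replicate 5. The counts moved by over 1.5 times to 1191 higher and 1143 lower at an adjusted p under 0.01, to 77 and 81 with a 1.5-fold threshold (both stricter by construction), to 1239 lower with numbers 2, 3 and 5 only (fewer libraries), and to 3109 higher after GC content and length correction, where the cause was not tested. Lists called went from 9 to 0 with an estimated correlation and to 20 with fry, which asks another question. The replicate block gave 1561 higher, 1676 lower and 10 lists, with 2992 called genes shared with the unblocked fit, and called the sheath (adjusted p = 0.0372) and interferon (0.0316) lists. The same-number correlations of deviations were -0.06, 0.16 and 0.06, which show no clear pairing but cannot exclude it. No label says whether the numbers pair libraries. The growth factor list had an adjusted p of 0.0685 with the block, 0.0554 without Scx-positive replicate 5, 0.0568 without Scx-positive 5 and Scx-deleted 4, and 0.0513 with upper-quartile scaling, in a range of 1.24e-04 (fry) to 0.215 (estimated correlation), and also missed a threshold of 0.01. Of all genes called in the main fit, 66.1% were called again with numbers 2, 3 and 5 only, and 76.8% without Scx-deleted replicate 4 or 5. Named genes were mostly chosen for large changes or small p, so they were likely to stay called and do not stand for all calls. Among them 3132 of 3232 values stayed on the same side of the threshold, 59 lost it and 24 passed it. The other 17 changed sign, all in genes that did not pass the test. Mkx was at -0.0219 with upper-quartile scaling, -5.15e-04 with the stricter filter, -0.0189 with sample weights, -0.0953 with the replicate block, -0.0931 with numbers 2, 3 and 5 only, and -0.0104 with a surrogate variable. Mcam was at -0.0186 with the block and -0.0169 with numbers 2, 3 and 5 only. With sample weights Mylpf was at 0.109 and Tnnt3 at 0.0608. With each library left out Mkx ranged from -0.0946 to 0.0525, Mcam from -0.0199 to 0.117, Bop1 from -0.00459 to 0.0748 and Tnnt3 from -0.53 to 0.11, and the cause was not tested. Low counts limit Mylpf and Tnnt3, which were under 1 CPM. The fit with sex as a covariate was not run.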

Other observations

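The tests of the hypoxia-inducible factors were chosen after the result was seen, and the genes named here outside the naming rule were chosen after their values were seen. H19, an imprinted noncoding RNA, had a log2 change of -1.41 ± 0.14 (SE), from 18.3 ± 1.82 to 6.91 ± 1.99 CPM (SD, n = 4 each), and its neighbour Igf2, a fetal growth factor gene, -1.40 ± 0.27. Among 14 other tested genes of an imprinted network 7 were lower and 1 higher by edgeR, with Mest at -0.63, Meg3 at -0.59 and Plagl1 at -0.55, and Igf2r at 0.34. The fall of H19 and Igf2 may be part of a wider fall of this network, whose cause was not tested. Chance gives 2.03 lower, and the 1-sided Fisher exact p was 0.00178, which treats the genes as independent and so is too small if they move together.

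Called genes lay beside each other, changed in the same direction, more often than with shuffled positions. Mmp13, Mmp12, Mmp3 and Mmp10, within chromosome 9 from 7272514 to 7510240 of GRCm38, had log2 changes of 2.05, 3.37, 1.28 and 2.23. On chromosome 13 Ecm2, Aspn, Omd and Ogn, which lie within the Cenpp gene from 49464023 to 49652785, had -0.91, -2.10, -1.42 and -1.20, and Cenpp had -0.96. Cenpp, on the other strand, may share reads with them, since the use of strand is not given. Low counts limit Mmp12, at 0.141 CPM in Scx-positive and 1.54 CPM in Scx-deleted cells, and Omd, at 0.706 and 0.255 CPM. Both were below the mean of 2 CPM that the naming rule required. Over 9783 neighbouring pairs of tested genes 539 were called in the same direction, against a mean of 399.8 and a highest value of 472 in 10000 shuffles of positions (permutation p = 1e-04, the smallest they can give). Without pairs whose symbols share a stem the number was 490, against a highest value of 453, which argues against reads shared between like-named neighbours as the whole cause; paralogs with unlike names were not left out.

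Changes were not gathered around the deleted gene, where variants carried along with a targeted locus could lie. Within 10 Mb of Scx 46 of 208 genes were called (22.1%), against 28.7% of all others, an odds ratio of 0.705 with a 95% interval of 0.496 to 0.986 (Fisher exact p = 0.0368). The glycolysis and hypoxia list rose in both of its parts, with 12 of 17 genes of glucose uptake and glycolysis and 7 of 13 other targets of the hypoxia-inducible factors higher, while Vegfa was at -0.04 and did not pass. Activation of the hypoxia-inducible factors is a candidate explanation that these 7 genes do not decide, since they were known to rise with the list.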
